A study of Homo sapiens with 12 samples.

How the data were processed

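The samples were 12 sequencing libraries of SV-HUC-1, a human urothelial epithelial cell line immortalised with SV40. The cells had received DCBQ, a chlorinated benzoquinone that forms when drinking water is disinfected, or a blank solution, with harvest after 3 days. Per the labels, each condition had 3 reduced representation bisulfite (RRBS) libraries and 3 oxidative RRBS (oxRRBS) libraries, which makes 4 groups of 3. RRBS enriches CpG-rich parts of the genome. Bisulfite alone reads 5-methylcytosine (5mC) and 5-hydroxymethylcytosine (5hmC) together, whereas oxidation before bisulfite leaves 5mC as the reading. The labels do not say that libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

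Per the labels' protocols, genomic DNA was extracted with a QIAamp kit, and libraries were made with the Ovation RRBS Methyl-Seq system and the TrueMethyl oxidative bisulfite kit. Per the submitters' processing notes, the build was hg38 and the tools included cutadapt, Trim Galore and BSMAP 2.90. The role and settings of each tool are not given in the sources used here. The deposited values are a fraction per CpG, from 0 to 1, in one table of 5mC and one of 5hmC, each with 6 columns named by condition and number. Per the file names, these values are per CpG with a minimum of 5 reads, and the strands were merged. The authors' tables list no missing value and no depth, so the depth behind every fraction is unknown and no interval from read counts is given. All levels are printed here as percent.

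How the authors combined the libraries is not given in the sources used here. From the values, no 5hmC level lies below 0, and a bisulfite reading minus an oxidative reading set to 0 at each CpG does not account for all of them, since it would hold the sum of the marks at or below 1. Where 5mC was 0, between 19.99% and 23.83% of CpGs per sample had 5hmC above 0, and where 5mC was complete only 0.94% to 1.13% did. The sum of the levels exceeded 1, by more than a tolerance of 0.001, at 2.75% to 3.34% of the shared CpGs per sample. The levels therefore do not add up exactly, and the planned comparison of the summed level was not run. The 5mC table held 3689712 CpGs, the one of 5hmC 3534314, and 3533825 were in both. No column belonged to any other sample. No pair of columns was identical: correlations between samples across CpGs were 0.968 to 0.972 for 5mC and 0.197 to 0.231 for 5hmC.

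Gene positions came from a table of the GRCh38.p14 assembly with 20037 protein-coding genes of a single placement on chromosomes 1 to 22, X and Y. The table gave each gene's start and end without strand, exons or untranslated regions. The planned promoter, which needs the transcription start, was therefore replaced by the CpG-dense gene end. This is whichever gene end had more measured CpGs in a window from 1500 bp outside to 500 bp inside the gene. It can be the 3′ end of a gene. The gene body ran from 500 bp inside that end to the other end. Exons, introns, untranslated regions and CpG islands were not analysed here, and the density of measured CpGs per 1 kb tile, in quartiles of CpGs, stood in for islands.

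The mean level per sample was computed over all CpGs, by chromosome and by feature, and compared with a two-sided exact permutation test. With 3 samples against 3 there are 20 relabellings and the smallest possible p is 0.1, so this test cannot pass 0.05. Mean levels of gene ends, gene bodies and 1 kb tiles with at least 5 CpGs, and single CpGs whose value varied, were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on the untransformed level. The threshold was a Benjamini-Hochberg adjusted p of 0.05, and for single CpGs also a difference of at least 10 percentage points. Errors of differences are standard errors (SE), from limma for units and from the spread of sample means for global levels. The other numbers were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and plots with matplotlib 3.10.9.

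A total of 23 gene lists with 944 distinct genes, of which 939 were in the gene table, was fixed in advance. They covered DNA methylation and demethylation enzymes, NRF2 antioxidant targets, xenobiotic metabolism, iron handling and 2-oxoglutarate metabolism, bladder cancer drivers, genes often hypermethylated in urothelial tumours, WNT, PI3K-AKT, MAPK and TGF-beta signalling, cell adhesion, clustered protocadherins, HOX genes, other developmental transcription factors, imprinted genes, DNA repair, p53 targets and apoptosis, cell cycle, urothelial, fibroblast, and leukocyte and endothelial markers, germline genes and housekeeping genes. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over 92 tests.

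Genes were named by a rule. For each mark it took the gene ends that passed the threshold with the groups apart, the 10 largest differences in each direction. With fewer than 5 in a direction, those with the smallest p filled up to 5 and are said not to have passed. The same rule gave 5 gene bodies and 3 tiles per direction. Up to 4 members per described list with the largest moderated statistic could be named, and TET1, TET2, TET3, DNMT1, DNMT3A, DNMT3B, UHRF1, TDG, NQO1 and HMOX1 always were. A window shared by a pair of genes is named by both. Some results that the rule selects are not reported here.

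These choices, the lists and the alternatives were made before the data were examined, except where said otherwise. The alternatives left out each sample in turn and changed the minimum number of CpGs per unit, window, tile size, variance trend, transformation, median or mean level, chromosomes and single-CpG difference, or added the replicate number as a block. Bins of 100 kb, 1 Mb and 5 Mb with at least 50 CpGs were added after seeing the data, as were gene ends with at least 3 times the CpGs of the other end.

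The fits were tested on simulated data that kept each unit's mean and dealt its residuals to the samples at random, with 200 units changed by known amounts. Among 15751 simulated gene ends, the 5mC fit recovered 49.3%, 83.6% and 97% of changes of 5, 10 and 20 percentage points, and among 14845 gene bodies 59.7%, 89.6% and 98.5%. For 5hmC the shares were 1.5%, 16.4% and 100% among 15627 gene ends, and 34.3%, 89.6% and 98.5% among 14750 gene bodies. Tiles gave little: 6.1% of 5mC changes of 20 points among 210424 tiles and 0% of those for 5hmC among 201896. Among 300000 simulated single CpGs, 0% of 5mC changes of 60 points and 90.9% of such 5hmC changes were recovered, the latter with 1 false call. The real tests adjusted over more CpGs, 3419211 for 5mC and 3153705 for 5hmC. Changes were planted only in units away from both extremes of level, always towards the middle. These shares therefore need not hold for the real fits, least of all near the extremes.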

Results

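Methylation (5mC) and hydroxymethylation (5hmC) of single CpGs were profiled in SV-HUC-1 urothelial cells after 3 days with DCBQ or with a blank solution, with 3 samples per condition and mark. The design asks whether exposure to this disinfection byproduct alters either mark across the genome. Depth per CpG is unknown, and 3 samples per group limit the precision. All positions are hg38.

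The measured CpGs of the DCBQ samples read slightly less 5mC on average than those of controls, on every chromosome examined. RRBS covers mainly CpG-rich DNA, and where CpGs were densest the groups overlapped. Mean 5mC over 3689712 CpGs was 54.543% ± 0.154 (SD, n = 3) in controls and 54.127% ± 0.098 (SD, n = 3) after DCBQ, a difference of -0.416 percentage points (SE 0.105). The controls read 54.72%, 54.448% and 54.46% and the DCBQ samples 54.058%, 54.239% and 54.084%, so the groups did not overlap. The two-sided exact permutation p was 0.1, the smallest that 3 samples against 3 allow. Each of the 23 chromosomes examined, 1 to 22 and X, was lower in DCBQ with the groups apart, by -0.543 to -0.328 points. The chromosomes come from the same samples, so they are not separate tests. The share of CpGs with at least 80% 5mC was 41.93% in controls and 41.489% after DCBQ, also without overlap. On mitochondrial DNA, with 269 CpGs, 5mC read 1.19% ± 0.168 (SD) in controls and 1.143% ± 0.201 (SD) after DCBQ.

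**Figure D1:**
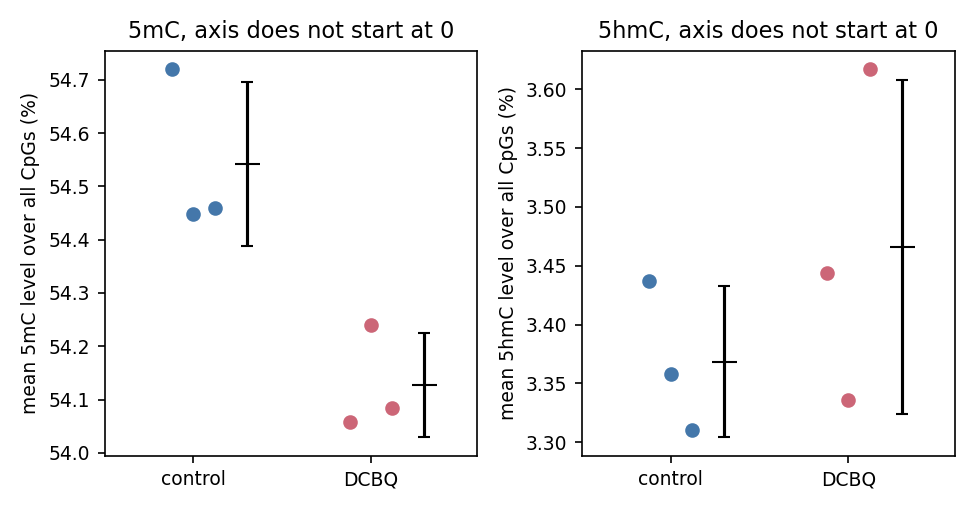
Mean 5mC (left) and 5hmC (right) level over all CpGs, in percent, with 1 point per sample (n = 3 per group) and the group mean and SD as a black bar. The 5mC points of DCBQ all lie below those of the controls (54.127% against 54.543%), whereas the 5hmC points overlap (3.466% against 3.368%).

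Among the 4 density quartiles, the difference was largest where CpGs are sparse. In the quartile of CpGs from tiles with 1 to 8 measured CpGs per 1 kb, mean 5mC was 70.732% in controls and 70.081% in DCBQ, a difference of -0.65 points (SE 0.151). In the quartile with 9 to 17 CpGs the difference was -0.534 points (SE 0.119), and with 18 to 45 CpGs it was -0.342 (SE 0.09). In the densest quartile, with 46 to 196 CpGs, it was -0.124 (SE 0.07) and the groups overlapped. Mean 5mC in controls was 72.578% with 9 to 17 CpGs, 51.401% with 18 to 45 and 23.419% in the densest quartile. Density and level are therefore not told apart here. CpG-dense gene ends had low 5mC, 15.861% ± 0.076 (SD) in controls and 15.72% ± 0.083 (SD) in DCBQ, a difference of -0.14 points (SE 0.065). The rest of protein-coding gene spans differed by -0.443 points (SE 0.107) and DNA outside protein-coding genes by -0.549 (SE 0.134). Apart from the densest quartile, these features had non-overlapping groups and an exact permutation p of 0.1, adjusted p 0.233 over 14 tests.

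**Figure D2:**
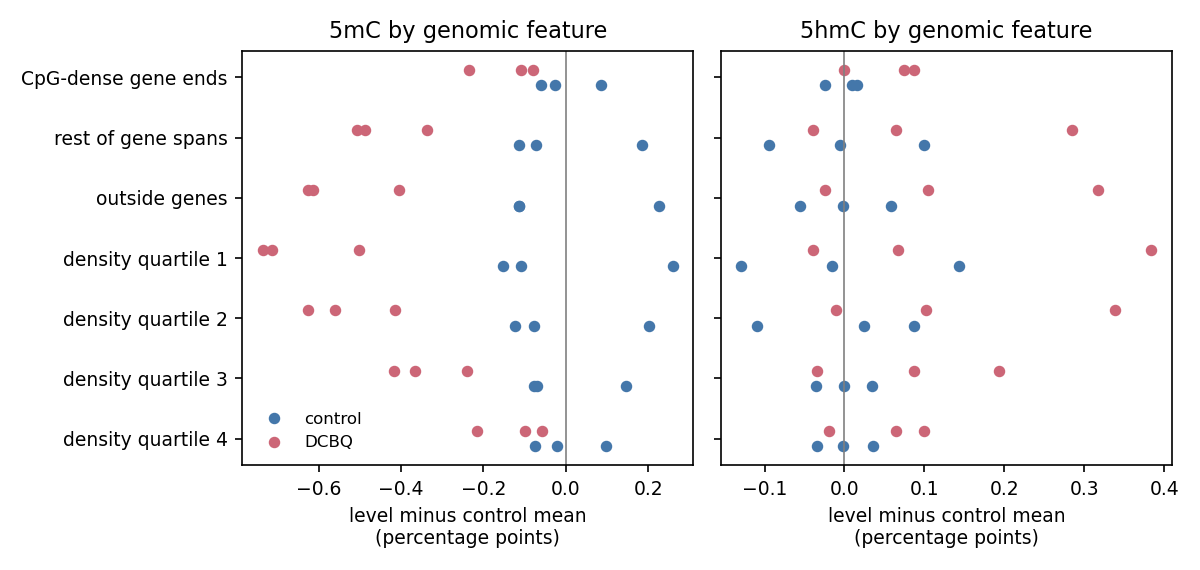
Level of each sample minus the control mean, in percentage points, for 5mC (left) and 5hmC (right) by feature, with control samples in blue and DCBQ samples in red (n = 3 each). Quartile 1 has the sparsest CpGs and quartile 4 the densest, with 5mC differences of -0.65 and -0.124 points.

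No single gene end or gene body passed the test for 5mC, although most differed downwards. Among the gene ends with the smallest p on the lower side were those of NEIL3, a DNA glycosylase that removes oxidised bases, NLRP2, CMKLR1 and SCFD2. On the higher side were the homeobox gene BSX, the retinoid receptor gene RXRG, the sphingomyelinase gene SMPD3, XKR7 and SYCE1L. The largest of these differences was at NLRP2 (chromosome 19, 54963784 to 54965784, in a window that overlaps NLRP7), with 71.76% ± 1.39 (SD) in controls and 62.87% ± 1.42 in DCBQ. None of these 9 passed (limma adjusted p = 0.476 for each).

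CMKLR1, a chemokine-like receptor gene, read 43.92% ± 1.37 (SD) in controls and 36.87% ± 0.66 in DCBQ at chromosome 12, 108338811 to 108340811. NEIL3, with only 6 CpGs at chromosome 4, 177308374 to 177310374, read 2.76% ± 0.5 and 0.26% ± 0.22, and SCFD2 read 2.21% ± 0.28 and 0.69% ± 0.24. In the other direction, SYCE1L read 72.14% ± 0.96 in controls and 78.03% ± 0.22 in DCBQ at chromosome 16, 77212715 to 77214715. BSX read 18.69% ± 0.75 and 23.7% ± 0.42 at chromosome 11, 122976070 to 122978070, and RXRG 15.65% ± 0.74 and 19.8% ± 0.38 at chromosome 1, 165444626 to 165446626. SMPD3 read 1.38% ± 0.16 and 2.76% ± 0.17, and XKR7 4.49% ± 0.1 and 7.84% ± 0.9. All 9 had non-overlapping groups.

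Of 15751 gene ends, limma called 0. An unadjusted p under 0.05, which chance alone gives at a share of about 0.05, was met by 1036 (6.58%). Of these, 714 were lower and 322 higher in DCBQ. Lower values made up 60.2% of all gene ends, and the groups were apart at 12%, where chance gives 10%.

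Among gene bodies, 10425 of 14845 (70.2%) were lower in DCBQ. The smallest p on the lower side belonged to HSBP1L1, N4BP2L1, the proteasome assembly chaperone PSMG3, the mRNA export factor THOC6 and the tyrosine aminotransferase TAT. On the higher side these were MPPE1, FAM43B, the paired-box gene PAX1, IAH1 and the constitutive heat shock protein HSPA8. HSBP1L1, whose span reaches into TXNL4A at chromosome 18, 79965143 to 79970822, read 93.51% ± 1.04 (SD) in controls and 84.76% ± 1.36 in DCBQ. None passed (limma adjusted p = 0.246 for the lower 5 and MPPE1, 0.318 for the other 4).

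TAT read 82.36% ± 0.95 and 75.56% ± 0.99, PSMG3 77.72% ± 0.82 and 71.32% ± 0.93, THOC6, overlapping HCFC1R1, 73.21% ± 0.53 and 68.92% ± 0.31, and N4BP2L1 16.96% ± 0.23 and 14.41% ± 0.1. MPPE1, which overlaps GNAL at chromosome 18, 11882622 to 11907817, read 78.06% ± 1.16 in controls and 85.57% ± 0.9 in DCBQ. IAH1, overlapping ADAM17, read 36.83% ± 1.09 and 42.06% ± 0.97, FAM43B 30.31% ± 0.37 and 32.71% ± 0.19, PAX1 21.22% ± 0.26 and 23.6% ± 0.41, and HSPA8 0.81% ± 0.09 and 2.28% ± 0.18. With limma, 0 gene bodies passed and 1295 (8.72%) had an unadjusted p under 0.05, of which 1066 were lower. The groups were apart at 16.3% of gene bodies, where chance gives 10%.

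**Figure D3:**
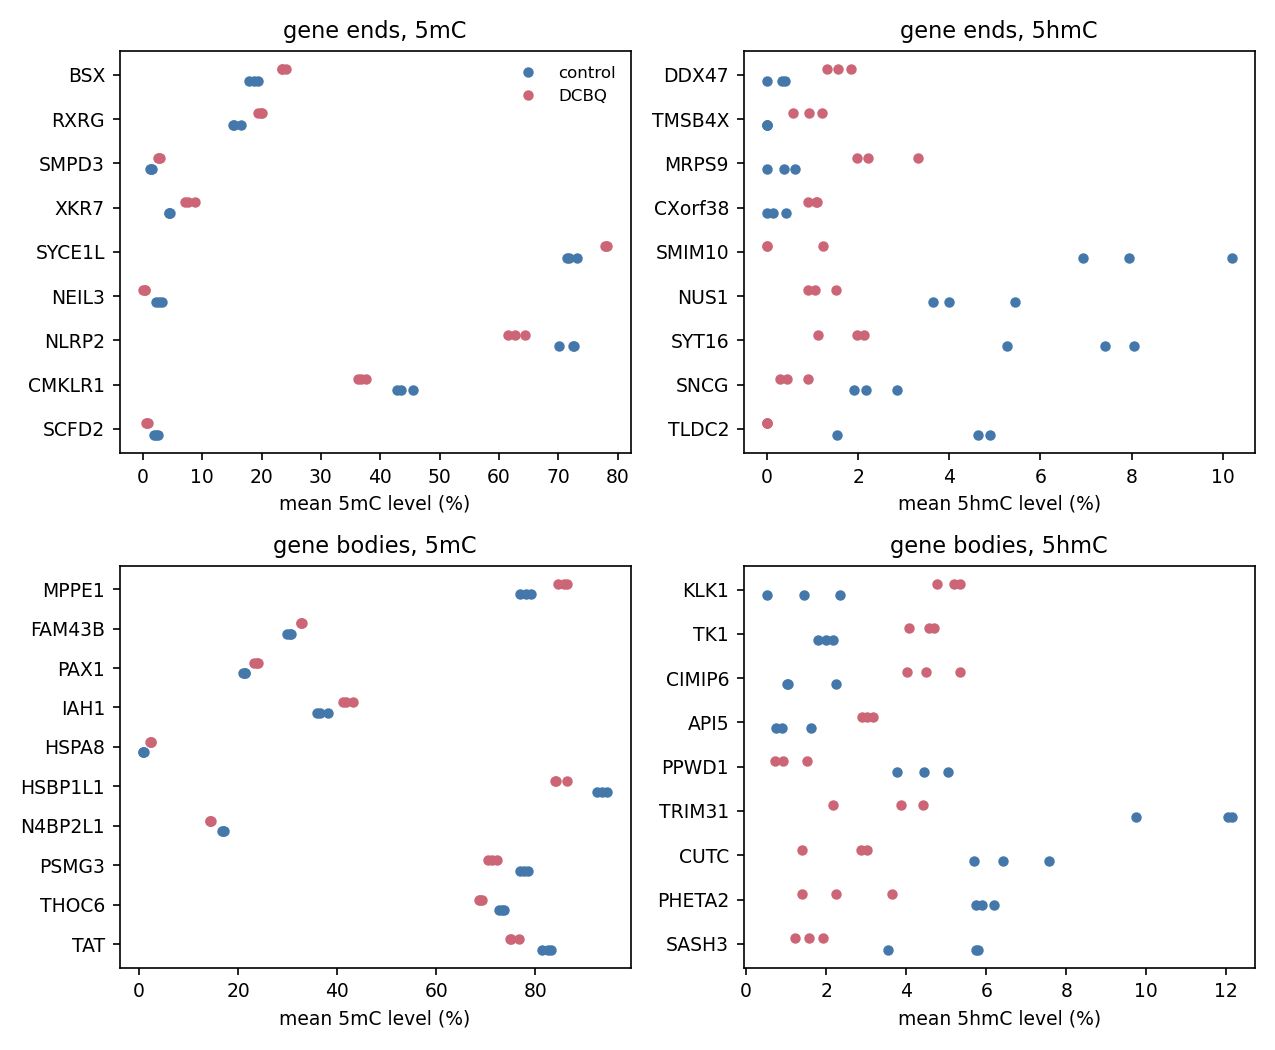
Mean level in percent of each sample (control blue, DCBQ red, n = 3 each) for gene ends (top) and gene bodies (bottom) among those with the smallest p in each direction, for 5mC (left) and 5hmC (right). The groups did not overlap at any of them and none passed the adjusted threshold; NLRP2, for example, read 71.76% in controls and 62.87% in DCBQ.

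Smaller units gave no 5mC call either. Of 210424 tiles of 1 kb, limma called 0 (smallest adjusted p 0.706), with 13041 (6.2%) at an unadjusted p under 0.05, and 59.9% were lower. The lower tiles with the smallest p lay in AGAP1 (chromosome 2, from 235703001), where 5mC read 4.51% in controls and 0.64% in DCBQ, and in HSBP1L1 (chromosome 18, from 79966001), where it read 97.69% and 81.75%, with another on an alternate contig of chromosome 6, 15.76% and 8.24%. The higher ones lay in ADAMTS2 (chromosome 5, from 179233001, 72.01% and 91.17%), at an end of STING1 (chromosome 5, from 139482001, 14.35% and 20.15%) and in TTC34 (chromosome 1, from 2697001, 3.48% and 10.05%). Of 3419211 single CpGs limma called 0, with 160342 (4.69%) at an unadjusted p under 0.05. That share is below 0.05, but other splits of the 6 samples gave at most 151561, so 0.05 is not a fair guide to chance here.

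Among the enzymes that write, read and remove 5mC, the dense ends of some differed little and others by several points. DNMT1, the maintenance methyltransferase, read 1.16% ± 0.44 (SD) in controls and 1.15% ± 0.23 in DCBQ, DNMT3A 12.7% ± 0.21 and 13.1% ± 0.84, and DNMT3B 7.65% ± 0.22 and 7.05% ± 0.46. The dioxygenase genes TET1 (5.47% ± 0.98 and 5.16% ± 0.36), TET2 (78.7% ± 6.33 and 79.23% ± 1.28) and TET3 (2.29% ± 0.5 and 2.68% ± 0.55) overlapped between groups. UHRF1, at its higher-coordinate end, read 72.01% ± 3.19 and 76.11% ± 1.65, SMUG1 23.88% ± 2.4 and 19.49% ± 2.71, and CXXC5 86.74% ± 1.27 and 83.67% ± 1.05, the last with the groups apart. TDG, whose window holds an end of UQCC6, read 1.12% ± 0.29 and 0.97% ± 0.32. The oxidative stress genes NQO1 (1.81% ± 0.57 and 1.13% ± 1.04) and HMOX1 (1.31% ± 0.19 and 1.16% ± 0.21) stayed near 0 in both. None passed (limma adjusted p from 0.714 for CXXC5 to 0.996 for DNMT1).

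Every gene list had more members lower than higher in DCBQ for 5mC, at gene ends and in gene bodies (23 of 23 lists each). This follows the direction of all genes, and no list stood apart from the other genes with camera (0 of 92 tests over both marks; 2 at an unadjusted p under 0.05). An estimated correlation also gave 0 calls (0 at an unadjusted p under 0.05), as did fry for a shift in 1 direction (10 unadjusted). No member of any list passed over all genes tested.

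The DNA methylation and demethylation enzymes had the lowest median difference of the 23 lists in gene bodies. In their gene bodies 5mC was lower at 22 of 26 measured members and higher at 4, with a median of -0.68 points (camera unadjusted p = 0.0287, adjusted p = 0.975; adjusted p = 0.979 with an estimated correlation). Examples were DNMT1, 83.38% ± 0.49 (SD) in controls and 81.23% ± 0.85 in DCBQ, the cell division gene CDCA7, 41.83% ± 0.37 and 38.5% ± 1.31, and the uracil glycosylase SMUG1, 65.46% ± 0.99 and 63.67% ± 0.54. At gene ends 18 of 28 were lower. No member passed when adjusted over the list alone.

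Genes of the response to reactive chemicals showed single members at most. Of NRF2 antioxidant targets, 14 of 25 gene bodies and 19 of 28 gene ends were lower. The end of thioredoxin, TXN, read 1.88% ± 0.33 (SD) in controls and 1.08% ± 0.42 in DCBQ. In the bodies 1 member was called when adjusted over the list alone, and at the ends 0. Of xenobiotic metabolism genes, 18 of 28 bodies and 18 of 26 ends were lower, with 1 member called for each when adjusted over the list alone. These were the glutathione transferase GSTA4 in its body, 81.53% ± 1.76 and 75.55% ± 1.19 (limma adjusted p = 0.0389), and the aldehyde dehydrogenase ALDH1A3 at its end, 3.76% ± 0.03 and 2.79% ± 0.09 (limma adjusted p = 0.0325). Adjusted over all bodies or ends, their limma p was 0.409 and 0.491. Of iron handling and 2-oxoglutarate genes, 28 of 37 bodies and 25 of 41 ends were lower, for example the end of ferritin FTH1 at 2.93% ± 1.14 and 1.52% ± 0.16, with 0 members called when adjusted over the list alone.

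Lists of urothelial cancer genes had more members lower than higher. Among genes often hypermethylated in urothelial tumours, 34 of 56 ends and 33 of 55 bodies were lower. IRAK3, a negative regulator of Toll-like receptor signalling, read 18.41% ± 0.29 (SD) at its end in controls and 21.52% ± 0.46 in DCBQ (chromosome 12, 66187714 to 66189714). It was the 1 member called when adjusted over the list alone (limma adjusted p = 0.0306; 0.491 over all). NID2 read 39.44% ± 0.73 and 41.46% ± 1.19 at its end, DAPK1 59.36% ± 0.34 and 57.63% ± 0.19 in its body, and GATA4 50.73% ± 0.32 and 49.4% ± 0.12 in its body. With fry in either direction this list passed for ends (adjusted p = 0.0113) and bodies (adjusted p = 0.00189), a test that does not compare it with other genes. Of bladder cancer drivers, 29 of 48 ends and 33 of 47 bodies were lower, with RHOB at 12.43% ± 0.26 and 10.99% ± 0.41 in its body and 0 members called when adjusted over the list alone. Among urothelial and epithelial markers, 17 of 26 ends and 17 of 26 bodies were lower, for example the uroplakin UPK3B at 68.58% ± 1.19 and 66.54% ± 0.36 in its body.

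Developmental genes held members that differed in both directions. Among clustered protocadherins, 25 of 39 ends and 28 of 42 bodies were lower. PCDHB3 read 80.69% ± 1.6 (SD) and 75.92% ± 1.04 at its end and 75.5% ± 0.52 and 72.52% ± 0.41 in its body, where it was the 1 member called when adjusted over the list alone (limma adjusted p = 0.0374, or 0.354 over all gene bodies). PCDHGB6 was higher at its end, 53.82% ± 0.28 and 57.64% ± 0.48. Protocadherin ends passed fry in either direction (adjusted p = 0.00335). Among other developmental transcription factors, 51 of 91 ends and 55 of 90 bodies were lower. PAX8 read 14.83% ± 2.9 and 7.34% ± 0.96 at its end and DLX3 29.72% ± 1.88 and 36.16% ± 2.49, while PAX1 in its body was the 1 member called when adjusted over the list alone (limma adjusted p = 0.0364, or 0.318 over all gene bodies). The bodies of this list passed fry in either direction (adjusted p = 0.0217). HOX genes were lower at 21 of 38 ends and 23 of 38 bodies, with the end of HOXA10 at 38.01% ± 2.08 and 34.86% ± 1.41, and imprinted genes at 18 of 31 ends and 16 of 28 bodies, with the end of DLK1 at 20.78% ± 0.79 and 22.63% ± 0.24.

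In DNA repair genes, 32 of 55 ends and 38 of 52 bodies were lower. NEIL3 (limma adjusted p = 0.005) and the excision repair endonuclease ERCC5 (limma adjusted p = 0.028) were the 2 ends called when adjusted over the list alone. Over all gene ends their limma adjusted p was 0.476 and 0.491. ERCC5 read 0.41% ± 0.14 (SD) in controls and 1.63% ± 0.33 in DCBQ at its end and 79.16% ± 1.04 and 75.66% ± 0.94 in its body. Ends of this list passed fry in either direction (adjusted p = 0.0306). Among p53 targets and apoptosis genes 28 of 39 ends and 28 of 41 bodies were lower, and among cell cycle genes 23 of 45 ends and 29 of 42 bodies, for example AURKB at its end, 7.65% ± 0.98 and 5.04% ± 0.62.

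Signalling and adhesion lists also had more gene bodies lower than higher. MAPK genes were lower at 43 of 54 bodies and 30 of 54 ends, PI3K-AKT and receptor kinase genes at 31 of 41 and 22 of 38, WNT genes at 35 of 54 and 34 of 56, and TGF-beta and epithelial-mesenchymal transition genes at 22 of 34 and 20 of 35. Cell adhesion genes were lower at 32 of 48 bodies and 34 of 48 ends. Examples in bodies were AKT2 at 85.33% ± 0.96 (SD) in controls and 83.3% ± 0.38 in DCBQ, fibronectin FN1 at 79.76% ± 0.69 and 76.29% ± 1.62, and the junction gene F11R at 74.37% ± 1.06 and 71.86% ± 0.63. In these lists 0 members were called when adjusted over the list alone.

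Markers of other cell types and germline genes also had more members lower than higher. Leukocyte and endothelial markers averaged 68.82% at their ends in controls and 68.28% in DCBQ, with 12 of 20 ends and 14 of 22 bodies lower. The T cell genes CD3D and CD3G, which share a window, read 84.14% ± 1.48 (SD) and 77.4% ± 3.21. Germline and cancer-testis genes averaged 69.06% and 68.33% at their ends, with 23 of 35 ends and 19 of 35 bodies lower (bodies, camera unadjusted p = 0.0475, adjusted p = 0.975, relative to other genes upward). Fibroblast markers were lower at 9 of 14 ends and 13 of 16 bodies. Housekeeping genes averaged 8.18% and 8.19% at their ends, with 18 of 31 ends and 20 of 25 bodies lower.

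The median and mean of a list differed in sign for 5mC at the ends of bladder cancer drivers, PI3K-AKT genes, TGF-beta genes, urothelial markers and housekeeping genes, and in the bodies of NRF2 targets and germline genes. Camera, which compares a list with the other genes, pointed against the list's own median for 10 of 23 lists at ends and 14 of 23 in bodies. The lists with no count given had 0 members called for 5mC when adjusted over the list alone.

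For 5hmC, the difference of the mean over all CpGs lay within the spread of the samples. The mean over 3534314 CpGs was 3.368% ± 0.064 (SD, n = 3) in controls and 3.466% ± 0.142 (SD, n = 3) in DCBQ, a difference of 0.098 points (SE 0.09; exact permutation p = 0.4). All 23 chromosomes examined were higher in DCBQ, by 0.016 to 0.161 points, but 0 had the groups apart. Sample 3 of DCBQ was the highest at 3.617%. Without it the mean difference was 0.022 (0.163 without sample 2 of DCBQ), and 18 chromosomes were higher and 5 lower, a count chosen after the results were seen. By feature, CpG-dense gene ends read 1.707% ± 0.022 (SD) and 1.761% ± 0.047, other gene spans 3.345% ± 0.097 and 3.447% ± 0.165, and DNA outside genes 4.335% ± 0.057 and 4.467% ± 0.173. The 4 density quartiles, from sparse to dense, differed by 0.138, 0.143, 0.083 and 0.048 points, and without sample 3 of DCBQ by 0.014, 0.045, 0.027 and 0.023. Without it, other gene spans differed by 0.012. No feature had the groups apart (exact permutation p of 0.3 or more).

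Among the gene ends with the smallest p for higher 5hmC were those of the RNA helicase gene DDX47, the thymosin gene TMSB4X, the mitochondrial ribosomal gene MRPS9 and CXorf38. For lower 5hmC they were SMIM10, NUS1, the synaptotagmin gene SYT16, the synuclein gene SNCG and TLDC2. SMIM10 (chromosome X, 134989491 to 134991491) read 8.36% ± 1.66 (SD) in controls and 0.41% ± 0.71 in DCBQ, the largest difference of these 9. It had a limma adjusted p of 0.501 and did not pass.

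SYT16 read 6.91% ± 1.46 and 1.75% ± 0.54, NUS1 4.36% ± 0.96 and 1.15% ± 0.32, TLDC2 3.68% ± 1.86 and 0 in each DCBQ sample, and SNCG 2.31% ± 0.49 and 0.54% ± 0.31. MRPS9 read 0.33% ± 0.31 and 2.49% ± 0.71, DDX47 0.24% ± 0.21 and 1.58% ± 0.27, and CXorf38, whose window holds an end of MED14, 0.19% ± 0.22 and 1.02% ± 0.11. TMSB4X was listed at 0 in all controls and read 0.9% ± 0.32 in DCBQ. None of these 8 passed (limma adjusted p from 0.891 to 0.96). Over 15627 gene ends limma called 0, with 785 (5.02%) at an unadjusted p under 0.05, and groups were apart at 9.9%, where chance gives 10%.

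Gene bodies among those with the smallest p were, for higher 5hmC, the kallikrein gene KLK1, the thymidine kinase gene TK1, CIMIP6 and API5, and for lower 5hmC PPWD1, TRIM31, CUTC, PHETA2 and SASH3. TK1 read 1.99% ± 0.2 (SD) in controls and 4.44% ± 0.32 in DCBQ, KLK1 1.44% ± 0.91 and 5.1% ± 0.3, CIMIP6 1.43% ± 0.71 and 4.61% ± 0.67, and API5 1.09% ± 0.47 and 3.02% ± 0.14. TRIM31 read 11.3% ± 1.35 and 3.49% ± 1.16, CUTC 6.56% ± 0.94 and 2.43% ± 0.89, PHETA2 5.94% ± 0.23 and 2.43% ± 1.13, SASH3 5.03% ± 1.29 and 1.56% ± 0.34, and PPWD1 4.41% ± 0.65 and 1.06% ± 0.41. None passed (limma adjusted p from 0.794 to 0.801). Limma called 0 of 14750 gene bodies, with 786 (5.33%) at an unadjusted p under 0.05, and groups were apart at 9.8%, where chance gives 10%.

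The TET and DNMT genes showed no 5hmC call at their dense ends. TET1 read 2.36% ± 0.83 (SD) in controls and 2.84% ± 0.71 in DCBQ, TET2 10.79% ± 4.01 and 6.65% ± 3.33, and TET3 1.11% ± 0.51 and 1.13% ± 0.68. DNMT1 read 0.73% ± 0.22 and 0.66% ± 0.13, DNMT3A 1.51% ± 0.2 and 1.17% ± 0.71, and DNMT3B 1.2% ± 0.25 and 1.16% ± 0.21. UHRF1 read 8.12% ± 3.14 and 3.79% ± 1.18, TDG with UQCC6 0.66% ± 0.16 and 0.98% ± 0.26, NQO1 1.11% ± 0.47 and 0.98% ± 0.52, and HMOX1 0.87% ± 0.27 and 0.94% ± 0.19. Their limma adjusted p lay between 0.971 and 0.999.

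By list, more members were higher than lower in 5hmC for 17 of 23 lists at gene ends and 16 of 23 in gene bodies, with 0 camera calls (0 at an unadjusted p under 0.05). The clearest members were imprinted genes. The bodies of PEG3 and ZIM2, which share CpGs on chromosome 19, read 3.77% ± 0.69 (SD) and 3.73% ± 0.76 in controls and 8.96% ± 0.92 and 8.39% ± 0.64 in DCBQ. They were the 2 members called when adjusted over the list alone (limma adjusted p = 0.014 for each; 0.794 over all), and PLAGL1 read 3.08% ± 0.6 and 5.53% ± 0.8. Of the 28 imprinted gene bodies 14 were higher and 14 lower, and the list passed fry in either direction (adjusted p = 0.0154). In gene bodies 5hmC was higher at 37 of 42 clustered protocadherins, for example PCDHB3 at 4.47% ± 0.46 and 6.36% ± 0.45, and at 21 of 26 DNA methylation and demethylation enzymes, where 8363 of all 14750 gene bodies were higher. Members of these lists vary together (estimated correlation 0.5263 and 0.1532), and camera gave an adjusted p of 0.975 for each, or 0.979 with the estimated correlation. Other examples were the body of FOXO3 at 1.98% ± 0.14 and 3.35% ± 0.29 among PI3K-AKT genes and of XPC at 2.03% ± 0.26 and 3.42% ± 0.46 among DNA repair genes. No other 5hmC list had a member called when adjusted over the list alone. Median and mean differed in sign at the ends of methylation enzymes, xenobiotic genes, tumour-hypermethylated genes, DNA repair genes, fibroblast markers, iron genes and housekeeping genes, and in the bodies of bladder cancer drivers. Camera pointed against the median for 3 lists at ends and 4 in bodies.

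Of 201896 tiles, limma called 0 for 5hmC, with 9747 (4.83%) at an unadjusted p under 0.05, no more than chance gives. Among the lower tiles with the smallest p were those near KIR3DL2 (chromosome 19, from 54869001, 12.15% in controls and 0.4% in DCBQ) and in COL4A2 (chromosome 13, from 110479001, 2.39% and listed at 0). Higher ones lay outside genes, nearest to DHRS7B (chromosome 17, from 21114001, 0.26% and 18.87%), FSCN1 (chromosome 7, from 5568001, listed at 0 and 11.11%) and WNK2 (chromosome 9, from 93347001, listed at 0 and 3.19%). They did not pass (limma adjusted p = 0.974).

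Of 3153705 single CpGs, 57259 (1.82%) had a limma unadjusted p under 0.05 for 5hmC. At least as many came in 9 of the 10 splits of the 6 samples, the real one included. Limma called 1 of the CpGs. It was position 102600710 of chromosome 8, outside protein-coding genes, 39692 bp from ODF1. Its 5hmC read 20.3%, 21.4% and 5.6% in controls and 75%, 72.2% and 60.7% in DCBQ, a difference of 53.5 points (SE 8; limma adjusted p = 0.00471). The 5mC there read 37.3% ± 11.247 (SD) and 4.767% ± 8.256, which is not separate support if both marks use the same oxidative reading. The 12 other CpGs within 500 bp averaged 6.618% ± 2.521 (SD) and 10.055% ± 4.345 of 5hmC, which overlapped. The call was lost when any 1 sample was left out, without the variance trend and with the replicate number as a block.

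Tiles with higher 5hmC in DCBQ tended to have lower 5mC there, to the same degree as between samples of a group. If 5hmC is computed by subtracting the oxidative reading that gives 5mC, this inverse relation arises from the measurement alone. Across 201907 tiles, which are not independent replicates, the differences of the marks had a Pearson correlation of -0.605, and the deviations within groups, where exposure plays no part, -0.626. The covariance of the differences was -2.991 squared percentage points, against -2.98 from the within-group noise alone.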

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

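Bins of 100 kb, 1 Mb and 5 Mb, those of 5 Mb also after a median shift, gene ends with at least 3 times the CpGs of the other end, and leaving out samples by chromosome and by 5mC level were chosen after the results were seen; the other alternatives were planned. With 5 Mb bins limma called 259 of 608 lower for 5mC and 2 higher for 5hmC, where 1 kb tiles gave 0. Shifted to the same median, which by construction removes a shared offset, 0 were called for each by limma, with 71 and 31 at an unadjusted p under 0.05. For 5hmC most of the difference stayed, 0.55 (limma SE 0.14) becoming 0.44 (SE 0.11) on chromosome 5 and 0.73 (SE 0.1) becoming 0.63 (SE 0.37) on chromosome 8, so removal of an offset does not by itself account for the loss. The prior degrees of freedom of limma went from infinite to 6.4, so its error estimate changed too. For gene ends, the arcsine scale called 1 for 5hmC, where the untransformed level gave 0; the cause was not tested. For single CpGs of 5hmC, the 1 call became 0 with the replicate number as a block, 0 without the trend and 0 to 0 over the samples left out, 4 with samples at the same mean and 3 on autosomes; the cause of these changes was not tested. Another 156 values of the main results were classed as unchanged. For counts this meant equal or within 1.5 times, which includes counts that stayed at 0. For global differences it meant the same sign, and for the correlation of the marks a move smaller than its jackknife SE. Over the 6 samples left out in turn, the global difference was -0.472 to -0.327 for 5mC and 0.022 to 0.163 for 5hmC; means over tiles gave -0.596 and 0.119. The 14 feature differences kept their sign, but leaving out 1 sample moved 2 of 7 for 5mC and 6 of 7 for 5hmC by more than 1.5 times, for example from -0.14 to -0.093 at dense gene ends (5mC, without sample 1 of DCBQ) and from 0.138 to 0.014 in the sparsest quartile (5hmC, without sample 3). Over the samples left out, 18 to 23 of 23 chromosomes were higher in 5hmC. Deviations of samples with the same number were hardly correlated (-0.039 to 0.025). Noise per unit could hide a pairing, so pairing by number is not excluded. Among the planned results the block changed only the single-CpG call. The block was not run on the 5 Mb bins or the arcsine scale. The named units were rerun without each sample, with the block, with other windows and minimums and after a median shift, but not on the arcsine scale, where 1 gene end whose values are not given here passed. Of 72, 59 kept their direction in all of these and 0 passed (limma adjusted p 0.0764 to 1); the other 13 are always-named genes, whose cause of change was not tested. With 1000 bp on each side, 5mC differed by 0.177 at TET1, -0.086 at TET2 and -0.076 at TET3, and 5hmC by 0.114 at TET2 and 0.034 at DNMT3A. After a median shift, DNMT1 5mC differed by 0.106 and TET3 5hmC by -0.01. Leaving out samples, the 5mC difference ranged from -0.82 to 0.154 at TET1, -2.876 to 3.385 at TET2, -0.14 to 0.247 at DNMT1, -0.069 to 0.735 at DNMT3A and -0.314 to 0.033 at TDG, and that of 5hmC from -0.27 to 0.403 at TET3, -0.147 to 0.056 at DNMT1, -0.18 to 0.064 at DNMT3B, -0.415 to 0.142 at NQO1 and -0.026 to 0.226 at HMOX1. No value could be had for missing CpGs (there are none), a 10-read minimum (no depth is given), negative 5hmC (none beyond rounding) or the summed level, which was not run with any of its alternatives because the levels do not add up. Depth per CpG is unknown, so what it limits could not be measured.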

Other observations

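The groupings of CpGs by level, the 5 Mb bins and the tests of explanations below were chosen after the results were seen. Grouped by mean 5mC over the 6 samples, CpGs of intermediate level differed most between the conditions. CpGs at 20% to 40% read 30.805% ± 0.559 (SD, n = 3) in controls and 29.707% ± 0.048 in DCBQ, a difference of -1.098 points (SE 0.324). Those at 40% to 60% differed by -0.917 (SE 0.29) and those at 80% to 90% by -0.542 (SE 0.163). Each had the groups apart (exact permutation p = 0.1). Without sample 1 of the controls, the differences at 20% to 40% and 40% to 60% were -0.786 and -0.652, with the groups still apart. For 5hmC the groups were apart only where 5mC was high: 4.643% ± 0.069 (SD) in controls and 4.939% ± 0.211 in DCBQ at CpGs of 70% to 95%, and 1.661% ± 0.01 and 1.753% ± 0.059 at those of 95% to 100% (exact permutation p = 0.1 for each). Without sample 3 of DCBQ these differences of 0.297 and 0.093 points fell to 0.186 and 0.059. At 70% to 95% the closest samples of the 2 groups lay 0.02 points apart. Across the CpGs of these 2 levels, listed 5hmC hardly repeated between samples, with mean correlations of 0.047 and -0.031 (0.408 and -0.023 for 5mC). Values at 0 made up 42.8% and 63.3% of the listed 5hmC. Whether these means follow 5hmC itself was not tested. At CpGs of 30% to 70% 5hmC read 6.69% in controls and 6.688% in DCBQ, a difference of -0.002 points (SE 0.281). It ran from -0.193 without sample 3 of DCBQ to 0.183 without sample 1 of the controls.

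In bins of 5 Mb, 601 of 608 (98.8%) had lower 5mC in DCBQ, and limma called 259, all lower, 242 of them with the groups apart. All bins come from the same samples and share any offset of a sample, so they are not separate results. After a shift to the same median, which by construction removes a shared offset, limma called 0 bins for 5mC. The 2 bins called for 5hmC, named after their values were seen, start at 160000001 of chromosome 5 (3.38% in controls and 3.93% in DCBQ, limma adjusted p = 0.0242) and at 145000001 of chromosome 8 (1.84% and 2.58%, limma adjusted p = 1.87e-11). The small p on chromosome 8 is not to be relied on. The prior degrees of freedom of this fit were infinite, so limma took no account of the spread of that bin. Its SE was 0.1 by limma but 0.53 from its own samples, and the groups overlapped, with 1.92%, 1.46% and 2.15% in controls and 2.08%, 3.56% and 2.1% in DCBQ. After that shift the 2 bins called for 5hmC differed by 0.44 (limma SE 0.11) and 0.63 (SE 0.37) instead of 0.55 (SE 0.14) and 0.73 (SE 0.1). The prior degrees of freedom were then 6.4, and limma called 0 for 5hmC, with 31 bins at an unadjusted p under 0.05. The 2 calls for 5hmC thus ended with most of each difference still there, on chromosome 5 with the groups still apart. The single CpGs that joined the 5hmC call on chromosome 8 under some alternatives, also named after their values were seen, were all lower in DCBQ. They were position 71299247 of chromosome 18 (68.52% and 6.06%), 81208674 of chromosome 17 (63.52% and 38.53%) and 137549564 of chromosome 9 (64.05% and 41.67%).

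The lower 5mC of the DCBQ samples may come from the exposure or from the libraries. Less complete bisulfite conversion in the controls is argued against, as the only cause, by CpGs of 0% to 5% 5mC. They differed by -0.067 points (SE 0.046), closer to 0 than the genome-wide -0.416, and by -0.092 to -0.027 over the samples left out. CpGs of 5% to 20% differed by -0.585 (SE 0.189), more than genome-wide, with the groups apart. A loss of methylated signal in proportion to the level would grow with the level. The differences grew up to CpGs of 20% to 40%, at -1.098 points (SE 0.324), and shrank above. CpGs of 90% to 95% differed by -0.482 (SE 0.161), more than genome-wide, and those of 95% to 100% by -0.158 (SE 0.039), less. The shrinking above 40% argues against such a loss as the only cause. The levels were grouped by the mean of the same samples, which limits these comparisons. Less complete oxidation in the controls stays open: if 5hmC is a difference of readings set to 0 at the floor, which the values do not fully bear out, it needs a 5hmC difference of 0.187 points, within the spread of the 0.098 measured (SE 0.09). By level the values part, with 0.297 measured (SE 0.128) for 0.296 needed at CpGs of 70% to 95% (0.186 for 0.245 without sample 3 of DCBQ), but 0.012 (SE 0.107) for 0.43 at those of 5% to 30%, measured minus needed -0.418 (SE 0.193; -0.55 to -0.255 over the samples left out). At CpGs of 30% to 70% the measured difference was -0.002 (SE 0.281) for 0.558 needed, measured minus needed -0.56 (SE 0.389). At those of 95% to 100% it was 0.093 (SE 0.034) for 0.058, and at 0% to 5% 0.002 (SE 0.015) for 0.016. Depth per library is unknown, and the labels name no batch. A difference between cultures other than the exposure was not tested, so an effect of DCBQ remains a hypothesis.

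The 6 samples of a mark can be split 3 against 3 in 10 ways, the real split included, which is too few for a share under 0.05. For 5mC, 1 of 10 splits, the real one, gave as many units at an unadjusted p under 0.05 by limma: 1036 gene ends against 799 in the highest other split, 1295 gene bodies against 807, 13041 tiles against 11112 and 160342 CpGs against 151561. The same held for the 259 bins of 5 Mb called, against 5. As many such bins called for 5hmC as the real 2 came in 5 of 10 splits, with up to 4. For 5hmC, 1 of 10 gave as many gene ends (785 against 775), 4 as many gene bodies (786 against 947), 7 as many tiles (9747 against 10805) and 9 as many CpGs (57259 against 59574). As many single CpGs called for 5hmC as the real 1 came in 4 of 10, with up to 2. Lists with an unadjusted camera p under 0.05 numbered 2 for 5mC (6 of 10 splits gave as many, up to 4) and 0 for 5hmC (10 of 10, up to 3), and fry in either direction called 6 (1 of 10, against 5).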
